A study of Homo sapiens with 4 samples.

How the data were processed

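RNA from SNU484 gastric cancer cells was extracted with Trizol and labelled with Cy3 as cRNA, per the labels' protocols, and hybridized to 4 one-colour Agilent arrays of design 026652, with 1 array in each of 4 groups: GFP in normoxia, GFP in hypoxia, G9a in normoxia and G9a-dSET in normoxia. Per the file headers, the arrays were read with Feature Extraction 11.5.1.1 under protocol GE1_1105_Oct12. The deposited array files hold intensities on a linear scale: the raw spot median, the local background and a processed intensity after background subtraction and detrending by the extraction software, with no normalization between arrays, per the file headers. They also hold the software's error for the processed signal, and marks for spots that are saturated, outliers or well above background, per the file headers. The authors' value table holds linear intensities that equal the processed signal divided by 1 number per array (322, 424, 367 and 108 in the order above, within 0.01 on the log2 scale for 99.8%, 99.7%, 99.4% and 99.7% of the probes tested); how the authors chose these numbers is not stated in the labels.

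Each array had 43118 spots. Control spots and spots marked as outliers (242, 346, 594 and 306 per array) were left out, and 0 spots were saturated. The log2 of the processed signal was averaged over the spots of each of 34127 probes, and the 75th percentile of all probes of an array was subtracted. Probes were named through their RefSeq accession without its version and the reference table, which named 25771 probes of 19740 genes; 8356 probes had no name and were left out of the gene results. Coordinates are not given, because the file headers name another genome build (hg19) than the reference (GRCh38.p14), which was used for names only. For the 4994 genes with several probes, the probe with the highest mean over the 4 arrays was used.

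A gene entered a comparison if its probe was well above background on at least 1 of the 2 arrays. Where it was so on only 1, the difference was taken against the lowest level well above background on the other array, or the gene's own value there if higher, and is given as a lower bound ("at least"). The comparisons were hypoxia against normoxia, G9a against GFP, G9a-dSET against GFP and G9a against G9a-dSET. With 1 array per group no test across genes was possible, so genes are counted at a difference of at least 2-fold, with no p-value. The error given for a gene combines the software's errors on the 2 arrays. The number of arrays limits precision: these errors hold the scanner's and spot-to-spot error and none of the variation between cultures. The median SD of repeated spots was 0.06, 0.06, 0.04 and 0.07 on the log2 scale in the order above. On the raw spot median minus the local background it was 0.18, 0.19, 0.08 and 0.22. The lowest signal well above background was 14.1, 25.2, 24.7 and 5.42.

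Genes named in the text were chosen by a rule fixed before the values were seen: per comparison, the 10 largest increases and 10 largest decreases among genes with an official symbol, well above background on both arrays and with no probe of opposite sign; the 5 largest lower bounds in each direction; EHMT2 and EHMT1; genes lower in both hypoxia and G9a; and members of 37 gene lists fixed beforehand (832 genes, of which 813 were on the array). Each list's median difference was placed among those of 10000 random lists of the same size, matched on expression in 20 bins, with members known only by a bound above 1-fold counted at that bound and other dim members left out. This range describes the genes of 1 pair of arrays and is not a test between groups. Genes shared by 2 comparisons were counted against the number expected from independent lists, and the effect of a shared control array on the correlation was set against 100 simulations of unchanged arrays, with noise from repeated spots or as wide as the spread between the hypoxia and normoxia arrays. A gene was counted as not shared with G9a-dSET if it was compared there, no difference of at least 1.5-fold in that direction was found or could be given, and it differed by at least 1.5-fold between G9a and G9a-dSET.

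The calculation was tested on simulated data with 200 changed genes, of which 100 were changed 2-fold and 100 4-fold; this test was written after the calculation had first been run on the arrays. For hypoxia against normoxia, with 14813 genes in the step, the median recovered log2 difference was 0.98 for 2-fold genes and 2.03 for 4-fold genes, and 0 of 13441 unchanged genes reached 2-fold. For G9a against GFP, with 14813 genes, these were 1.05, 2.08 and 1 of 13218. For G9a-dSET against GFP, with 14799 genes, they were 1.04, 2.01 and 1 of 14012, and for G9a against G9a-dSET, with 14037 genes, 0.97, 1.98 and 0 of 13230. Of the genes changed 2-fold and measured on both arrays (91, 92, 97 and 97), 49.5%, 55.4%, 60.8% and 45.4% reached 2-fold in these comparisons, in this order. The recovered medians were also taken over changed genes measured on both arrays, with the other changed genes left out. Both simulated arrays of a comparison were built from the same real array. Their noise was that of the software's error model (SD per array of 0.17, 0.17, 0.16 and 0.18 on the log2 scale), with no variation between cultures or slides. The counts of unchanged genes at 2-fold are therefore no rate of false calls on the real arrays.

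The alternatives tried were quantile normalization, cyclic loess, the authors' value table, no filter on dim probes, detection on both arrays, the mean over a gene's probes, and limits of 1.5-fold and 3-fold. Chosen after the data were seen were normexp background correction of the spot median (offset 50, with 2 spots far below their background left out), 1 common detection floor, the 75th percentile over probes above background on all arrays, and the hypoxia array as reference. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, matplotlib 3.10.9 for figures, and R 4.3.3 with limma 3.58.1 for quantile, loess and normexp.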

Results

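Gene expression was measured in SNU484 cells, an established human gastric cancer cell line, on 4 arrays with 1 array in each of 4 groups. Cells carrying a GFP vector were kept in normoxia or in hypoxia, and cells in normoxia carried GFP-tagged G9a or a GFP-tagged G9a that lacks the SET domain (G9a-dSET). G9a, encoded by EHMT2, is a histone methyltransferase whose SET domain holds its catalytic activity. The stated aim was to find genes that go down in hypoxia or when G9a is overexpressed. Each array gave values for 34127 probes at most, of which 66.9% were well above background on the normoxia array, 59.3% on the hypoxia array, 59.1% on the G9a array and 62.1% on the G9a-dSET array. The G9a-dSET array was the dimmest, with a 75th percentile of signal of 183 against 668 on the normoxia array. No group had a replicate, so no difference below has a replicate check, and differences are given as log2 values with the error of the scanner's error model for a pair of spots. The normoxia and hypoxia arrays lay on slide 1, the G9a array on slide 2 and the G9a-dSET array on slide 3, so construct and slide cannot be told apart.

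The overexpressed gene was read first. The EHMT2 probe (A_23_P214638) was 12.4-fold higher on the G9a array than on the GFP normoxia array (log2 difference 3.63, error 0.20). In hypoxia it was 0.50 higher on the log2 scale (error 0.20), but only 0.0027 higher in the authors' value table. On the G9a-dSET array it stood -0.05 from GFP (error 0.20). The position of this probe in the transcript is not given in the sources used here, and it may lie in the deleted part, so it checks nothing about expression of G9a-dSET. EHMT1, which encodes the partner methyltransferase GLP, differed from GFP by -0.52 on the G9a array and by 0.22 on the G9a-dSET array (error 0.20 each) at its brightest probe. Its direction depended on the probe: A_23_P20894 stood at 0.41 with G9a (error 0.27) and A_33_P3286387 at -0.56 with G9a-dSET (error 0.23).

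**Figure D1:**
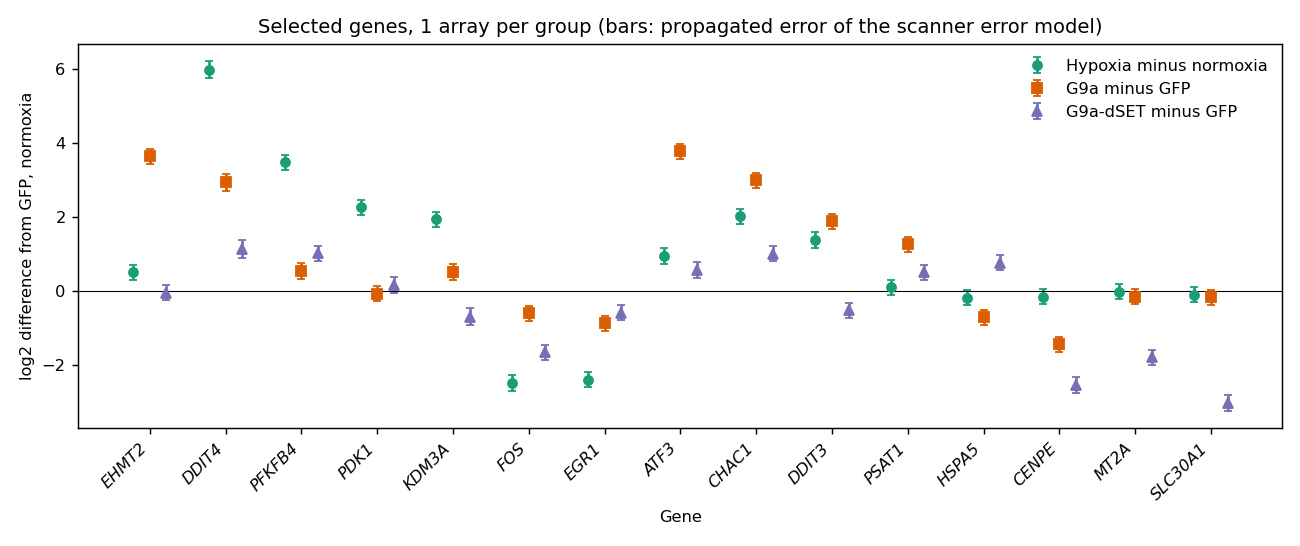
Log2 difference from the GFP normoxia array (vertical axis) for 15 genes (horizontal axis) on the hypoxia, G9a and G9a-dSET arrays, 1 array per group; bars give the propagated error of the scanner's error model. DDIT4 was highest in hypoxia at 5.97, EHMT2 stood at 3.63 on the G9a array and at -0.05 on the G9a-dSET array, and SLC30A1 was lowest on the G9a-dSET array at -3.03.

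In hypoxia, the list medians of targets of the hypoxia-inducible factors (HIF) were higher and that of growth-factor-induced immediate early genes was lower than in normoxia. The largest measured increase was that of DDIT4, an inhibitor of mTORC1 signalling, at 62.8-fold (log2 difference 5.97, error 0.23). ANKRD37 was 24.4-fold higher, the glycolytic regulator PFKFB4 11.1-fold, the pyruvate dehydrogenase kinase PDK1 4.77-fold and the glucose transporter SLC2A1 4.33-fold. EGR4 stood at -3.46 on the log2 scale, and the transcription factors FOS and EGR1 were 5.61-fold and 5.30-fold lower (errors of 0.20 to 0.23 on the log2 scale for these genes). In all, 144 of 14448 genes were at least 2-fold higher and 60 were at least 2-fold lower.

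Of 23 compared HIF targets in glycolysis and glucose uptake, 10 were at least 1.5-fold higher and 0 lower; the median log2 difference was 0.40, against a middle 95% of -0.09 to 0.06 among 10000 random lists matched on expression. HK2, the hexokinase of glycolytic tumours, was higher by 2.03, PGK1 by 0.88 and LDHA by 0.58. Of 39 other HIF targets, 25 were at least 1.5-fold higher, with a median of 0.86; they included HILPDA (2.01), BNIP3 (1.97), ANGPTL4 (1.84) and the angiogenic factor VEGFA (1.58). The transferrin receptor TFRC was the only one of these 39 at least 1.5-fold lower, at -1.12. Histone demethylases had a median of 0.29 (random lists -0.13 to 0.12), with KDM3A at 1.93 and KDM4B at 1.03; both removers of methyl groups from histone H3 were also members of the HIF list. Of 21 genes of the unfolded protein and integrated stress responses, 8 were at least 1.5-fold higher, among them CHAC1 (2.01), DDIT3 (1.37) and ATF3 (0.94), and the list median was 0.14 (random lists -0.11 to 0.06).

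Of 22 immediate early genes, 12 were at least 1.5-fold lower and 0 higher (median -0.64, random lists -0.13 to 0.08), with FOSL1 at -1.58, DUSP6 at -0.90, MYC at -0.75 and JUN at -0.62. Inflammatory cytokines and NF-kB targets had a median of -0.47 (random lists -0.20 to 0.13), with the chemokine CXCL1 at -1.07 and LIF at -0.90. Ribosome biogenesis genes had a median of -0.23 (random lists -0.09 to 0.05), with RRS1 at -1.07 and NOP56 at -0.61. DNA replication genes had a smaller median of -0.12 (random lists -0.09 to 0.04), with GINS3 at -0.82 and CDC6 at -0.77. CDKN1A, the cell-cycle inhibitor p21, stood at -1.45, whereas the list of p53 targets had a median of -0.05, inside the range of random lists. Nuclear-encoded oxidative phosphorylation genes (median -0.01, with 0 of 36 at least 1.5-fold different), cytosolic ribosomal proteins (median -0.01) and epithelial markers (median 0.07) also lay inside the ranges of their random lists.

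The split of genes in hypoxia depended on the limit and on the scaling. At a limit of 1.5-fold, 353 genes were higher and 398 lower, so the larger side turned. In the authors' value table, each array is divided by its own number and 55 genes were at least 2-fold higher and 579 lower, in place of 144 and 60 (with normexp, 47 and 18); that scaling moves the median of all genes in hypoxia by -0.50 on the log2 scale, and every list value given here is relative to the 75th percentile of each array. Of the 14448 genes, 1313 were detected on only 1 of the 2 arrays, and for 848 of these no bound above 1-fold could be given.

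**Figure D2:**
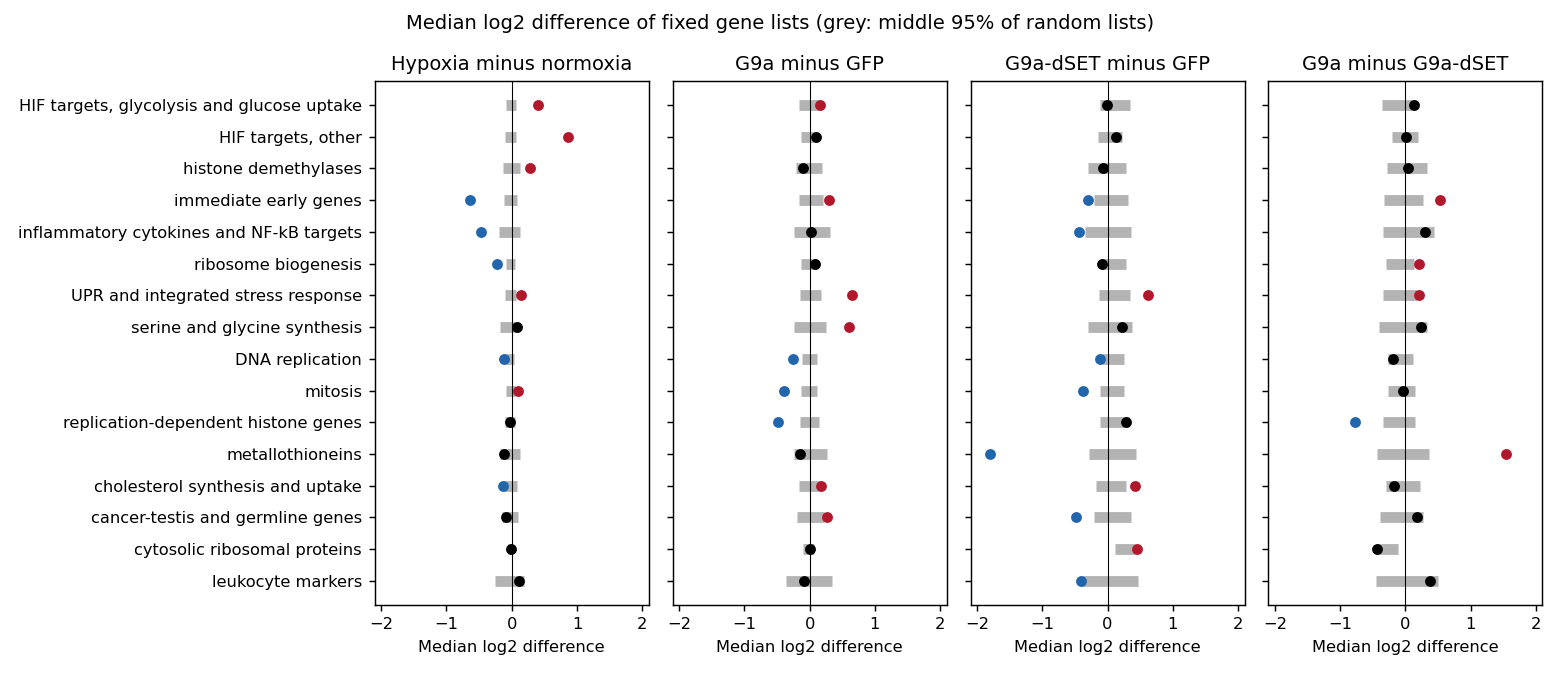
Median log2 difference (horizontal axis) of 16 gene lists (vertical axis) in the 4 comparisons; grey bars give the middle 95% of 10000 random lists matched on expression, and points outside it are red (above) or blue (below). In hypoxia the other HIF targets stood at 0.86 and immediate early genes at -0.64; metallothioneins stood at -1.80 on the G9a-dSET array, where the point for ribosomal proteins (0.45) turned negative with quantile normalization (-0.07).

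With G9a, the list medians of the unfolded protein and integrated stress responses and of serine synthesis were higher than with GFP; those of mitosis, DNA repair and replication-dependent histones were lower, though most members of these lists were less than 1.5-fold different. ATF3, a stress-induced transcription factor, was 13.7-fold higher (log2 difference 3.77, error 0.21), CHAC1, a glutathione-degrading enzyme induced by ATF4, 7.95-fold, and DDIT4 7.66-fold. ACTL6B, a neuronal subunit of BAF chromatin remodelling complexes, was 12.4-fold higher, and MROH5 stood at 3.70 on the log2 scale. Among lower genes, LCE1E stood at -2.63, the proteasome activator subunit PSME2 at -2.39 and the centromere motor CENPE at -1.45 (errors of 0.20 to 0.28). Among 14600 genes, 490 were at least 2-fold higher and 94 lower.

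Of the 21 stress response genes, 11 were at least 1.5-fold higher and 3 at least 1.5-fold lower (median 0.65, random lists -0.15 to 0.17). The higher members included TRIB3 (2.32), NUPR1 (2.28), SESN2 (1.90), DDIT3 (1.88) and ASNS (1.39), which are targets of ATF4. The 3 lower members were chaperones and folding factors of the endoplasmic reticulum, PDIA4 (-0.85), HSPA5 (-0.71) and SDF2L1 (-0.70). Serine and glycine synthesis genes had a median of 0.61 (random lists -0.24 to 0.25), with 6 of 10 at least 1.5-fold higher, among them PSAT1 (1.26), MTHFD2 (0.75) and PHGDH (0.59). Immediate early genes had a median of 0.30 (random lists -0.16 to 0.20), with JUN at 1.25 and JUNB at 0.86 but EGR1 at -0.88. Antigen presentation genes had a median of 0.32 (random lists -0.18 to 0.22), with HLA-E at 0.83.

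Of 34 mitosis genes, 7 were at least 1.5-fold lower and 0 higher (median -0.39, random lists -0.13 to 0.11), including KIF11 (-0.80) and MAD2L1 (-0.78). Replication-dependent histone genes had a median of -0.49 (random lists -0.14 to 0.14), and 5 of 22 were at least 1.5-fold lower, with H2AC13 at -0.70 and H3C10 at -0.68. DNA repair genes had a median of -0.29 (random lists -0.17 to 0.15), and 5 of 24 were at least 1.5-fold lower, with BRCA2 at -1.07 and XRCC2 at -0.90. DNA replication genes had a median of -0.25 (random lists -0.12 to 0.11), and 2 of 38 were at least 1.5-fold lower, with RRM2 and MCM10 both at -0.92. Markers of fibroblasts had a median of -0.56 over 8 genes (random lists -0.31 to 0.33); COL1A1 stood at -1.08 and DCN at -1.07, while DPT stood at 0.66. The list of genes reported to be repressed by G9a, or in hypoxia through G9a, had a median of 0.12 (random lists -0.19 to 0.18), with 2 of 18 genes at least 1.5-fold higher and 0 lower. In it, the tumour suppressor RUNX3 stood at 0.54.

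For G9a against GFP, the authors' value table gave 227 genes higher and 1089 lower in place of 490 and 94, with all genes moved by -0.50 on the log2 scale; normexp gave 203 higher and 22 lower, and 293 were higher with detection required on both arrays. Of 48 genes at least 2-fold different that had another probe above background, 21 had a probe with the opposite sign, and these were left out of the genes chosen by size.

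On the G9a-dSET array, the list medians of metallothioneins and mitosis genes were lower than with GFP, and those of the same stress response list and of cholesterol synthesis were higher; most mitosis and cholesterol synthesis genes were less than 1.5-fold different. The zinc exporters SLC30A1 and SLC30A2 were 8.15-fold and 8.16-fold lower (log2 differences of -3.03 each, errors 0.21 and 0.35), and the metallothionein MT1E, a metal-binding protein, was 4.03-fold lower. CENPE was 5.84-fold lower. RFPL4B was 76.0-fold higher, TMEFF2 17.1-fold and the WNT receptor FZD8 10.6-fold (errors 0.32, 0.27 and 0.24 on the log2 scale). All 3 were dim with GFP, at normalized log2 levels of -4.70, -4.58 and -4.31 on the normoxia array. The lowest level well above background there was -5.57. RFPL4B and TMEFF2 were not well above background on the hypoxia and G9a arrays. In all, 626 of 14613 genes were at least 2-fold higher and 391 were at least 2-fold lower.

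Of 9 compared metallothioneins, 7 were at least 1.5-fold lower (median -1.80, random lists -0.29 to 0.44), with MT1M at -1.90, MT1X at -1.86 and MT2A at -1.80; MT1A (0.20) and MT3 (0.57) were not. Of the 21 stress response genes, 12 were at least 1.5-fold higher and 0 lower (median 0.62, random lists -0.13 to 0.34). TRIB3 stood at 1.45 and CHAC1 at 1.01, the chaperones PDIA4 at 0.84 and HSPA5 at 0.76, and DDIT3 at -0.53. Cholesterol synthesis and uptake genes had a median of 0.42 (random lists -0.18 to 0.28), with 8 of 22 at least 1.5-fold higher, including MVD (1.09), MVK (0.96) and SQLE (0.89). Of 34 mitosis genes, 10 were at least 1.5-fold lower (median -0.37, random lists -0.11 to 0.25), including TOP2A (-1.22), TPX2 (-0.99) and CCNA2 (-0.99).

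Immediate early genes had a median of -0.30 (random lists -0.20 to 0.31), with FOS at -1.66 and CCN2 at -1.11, and cancer-testis genes a median of -0.48 (random lists -0.21 to 0.36), with MAGEA12 at -1.04 and MAGEA1 at -0.95. With normexp background correction these medians were 0.03 and 0.04, so their direction was not kept. Over members measured on both arrays they were -0.20 and -0.28. The normexp offset of 50 was the same on all arrays, while the median signal was 21.2 on the G9a-dSET array and 77.1 on the normoxia array. Whether this offset turned the medians was not tested, so normexp does not decide their direction. Inflammatory cytokines and NF-kB targets had a median of -0.44 (random lists -0.35 to 0.36), which became 0.44 with normexp and -0.21 over the 11 members measured on both arrays, inside the range of their random lists. Cytosolic ribosomal proteins had a median of 0.45 (random lists 0.11 to 0.42), which became -0.07 with quantile normalization. The co-stimulatory molecule CD86 was 7.71-fold higher and HLA-DPB1 6.92-fold, both of them genes of antigen-presenting cells. HLA-DPB1 was dim with GFP, at -5.01 on the normoxia array, where the lowest level well above background was -5.57. Leukocyte markers had a median of -0.41 over 9 genes (random lists -0.40 to 0.47). Of these, 1 was at least 1.5-fold higher, 1 at least 1.5-fold lower and 7 less than 1.5-fold different. Among the lower values were CD3E at -1.20, CD68 at -0.46, CD14 at -0.42 and PTPRC at -0.29. Over the 7 members measured on both arrays the median was -0.42, inside the range of their random lists. With normexp the list median was 0.19.

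For G9a-dSET against GFP, the authors' value table gave 297 genes higher and 1077 lower in place of 626 and 391, with all genes moved by -0.29, and normexp gave 1216 higher and 128 lower. Of 148 genes at least 2-fold different that had another probe above background, 52 had a probe with the opposite sign, and these were left out of the genes chosen by size.

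Full-length G9a was compared directly with G9a-dSET to set the protein with its catalytic domain against the one without. The arrays did not check that G9a-dSET was expressed. The list medians of immediate early genes and metallothioneins were higher with full-length G9a, that of replication-dependent histones was lower, and stress response genes went both ways. ACTL6B was 18.4-fold higher (error 0.25 on the log2 scale), ATF3 9.25-fold, SLC30A1 7.26-fold and CCNG2 6.07-fold. Against GFP, SLC30A1 stood at -0.17 with G9a and at -3.03 with G9a-dSET, so its difference lay on the G9a-dSET array. LCE1E stood at -3.50, PSME2 at -2.73 and the transcription factor RUNX1 at -2.71 (errors 0.28, 0.20 and 0.32). Among 13998 genes, 691 were at least 2-fold higher and 507 were at least 2-fold lower. At a limit of 1.5-fold, 1931 were higher and 1972 lower.

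Of 22 replication-dependent histone genes, 16 were at least 1.5-fold lower with G9a than with G9a-dSET and 0 higher (median -0.78, random lists -0.34 to 0.15), with H1-2 at -1.22, H2AC4 at -1.11 and H3C4 at -1.01. Of 21 immediate early genes with a value, 9 were at least 1.5-fold higher and 0 lower (median 0.53, random lists -0.33 to 0.27), with JUNB at 1.71, JUN at 1.32 and DUSP1 at 0.88. Metallothioneins had a median of 1.54 (random lists -0.44 to 0.36), with MT1M at 2.06 and MT2A at 1.64. Against GFP their median was -0.15 with G9a, inside the range of random lists, and -1.80 with G9a-dSET. The stress response list had a median of 0.22 (random lists -0.35 to 0.18) over members on both sides, with DDIT3 at 2.41 and CHAC1 at 1.98 against PDIA4 at -1.70, HSPA5 at -1.47 and HSP90B1 at -1.16. The genes reported to be repressed by G9a had a median of 0.46 (random lists -0.35 to 0.26), with 7 of 17 at least 1.5-fold higher and 1 lower. These arrays share neither slide nor scan day, the authors' value table gave 381 genes higher and 1065 lower, and normexp gave 191 higher and 514 lower.

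The stated aim concerned genes lower in hypoxia or with G9a, and genes lower in both were counted here. At least 2-fold lower in both were 4 genes, FAM83A, LCE4A, BTBD8 and RXRG, where 0.392 were expected if the lists were independent among the 14403 genes compared in both. FAM83A, which encodes a signalling protein of the EGFR pathway, was at least 4.28-fold lower in hypoxia and at least 3.78-fold lower with G9a. All 4 were also at least 2-fold lower on the G9a-dSET array. FAM83A, LCE4A and BTBD8 were well above background on the normoxia array alone, and RXRG on the normoxia and hypoxia arrays alone. At least 1 difference of each gene is therefore a lower bound. All these differences use the same normoxia array, so a high value there alone would make a gene lower in each. The number expected from independent lists does not allow for this, and the simulations below cover only genes well above background on all arrays. Measured on all arrays and lower in both were 0 genes. Genes lower in both but not on the G9a-dSET array numbered 0.

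At least 2-fold higher in both hypoxia and G9a were 12 genes, where 2.06 were expected from independent lists. They included DDIT4, CHAC1, the cyclin CCNG2 (1.52 in hypoxia and 2.47 with G9a), DDIT3, the transcriptional regulator CREBRF (1.30 and 1.46) and the circadian repressor NFIL3 (1.76 and 1.07). On the G9a-dSET array, DDIT4 (1.13), CHAC1 (1.01), ANKZF1 (0.98), OLIG1 (0.90) and NFIL3 (0.70), all among the 12, were also at least 1.5-fold higher than with GFP. There CCNG2 (-0.13), CREBRF (0.50) and DDIT3 (-0.53) were not at least 1.5-fold higher than with GFP. CCNG2, CREBRF and DDIT3 were at least 1.5-fold higher with G9a than with G9a-dSET. For CALHM3, PDE2A, LINGO3 and TSPAN19, also among the 12, no difference between G9a-dSET and GFP could be given, as they were too dim. ANKZF1, CREBRF, NFIL3, OLIG1, PDE2A, LINGO3 and TSPAN19 were chosen after their values were seen. Across 12727 genes, which are not independent replicates, the differences in hypoxia and with G9a had a Pearson correlation of 0.186 and a covariance of 0.0218; the correlation lay below that of simulated unchanged arrays (0.425 and 0.499 for the noise levels given next). Both use the same normoxia array, and unchanged arrays simulated with repeated-spot noise gave a covariance of 0.00434, with 0 genes lower and 0 higher in both, against 0 lower and 8 higher among these 12727 genes. Noise as wide as the spread between the hypoxia and normoxia arrays, which holds the differences of hypoxia itself and is no level of no change, gave a covariance of 0.0234, with 0.04 genes lower and 0 higher in both on average. The repeated-spot noise was that of the processed signal, with a median SD of 0.06 on the normoxia array. On the raw spot median minus the local background this SD was 0.18, and noise of that size was not simulated. Differences between slides and outlying values of single genes on the shared array were not simulated either and are not excluded. In the pair without a shared array, hypoxia against normoxia and G9a against G9a-dSET, 2 genes were lower in both (1.90 expected) and 13 higher in both (3.80 expected), with a correlation of 0.0505. In opposite directions, 5 genes were lower in hypoxia and higher with G9a than with G9a-dSET (2.21 expected), and 5 the reverse (3.27 expected).

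Under the authors' value table, whose scaling moves both comparisons by -0.50, 105 genes were at least 2-fold lower in both hypoxia and G9a. From independent lists 43.8 were expected, a number that does not allow for the shared normoxia array. Of the 105 genes, 72 were measured on all 3 arrays. Of the 105, 37 were not shared with G9a-dSET. After scaling to the 75th percentile, 57 of the 105 were at least 1.5-fold lower in both comparisons, and 57 genes in all passed that limit. The move by -0.50 takes a gene at that limit past 2-fold, so this number follows from the scaling and checks nothing. The value table divides the processed signal by 322 on the normoxia array, 424 on the hypoxia array, 367 on the G9a array and 108 on the G9a-dSET array.

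**Figure D3:**
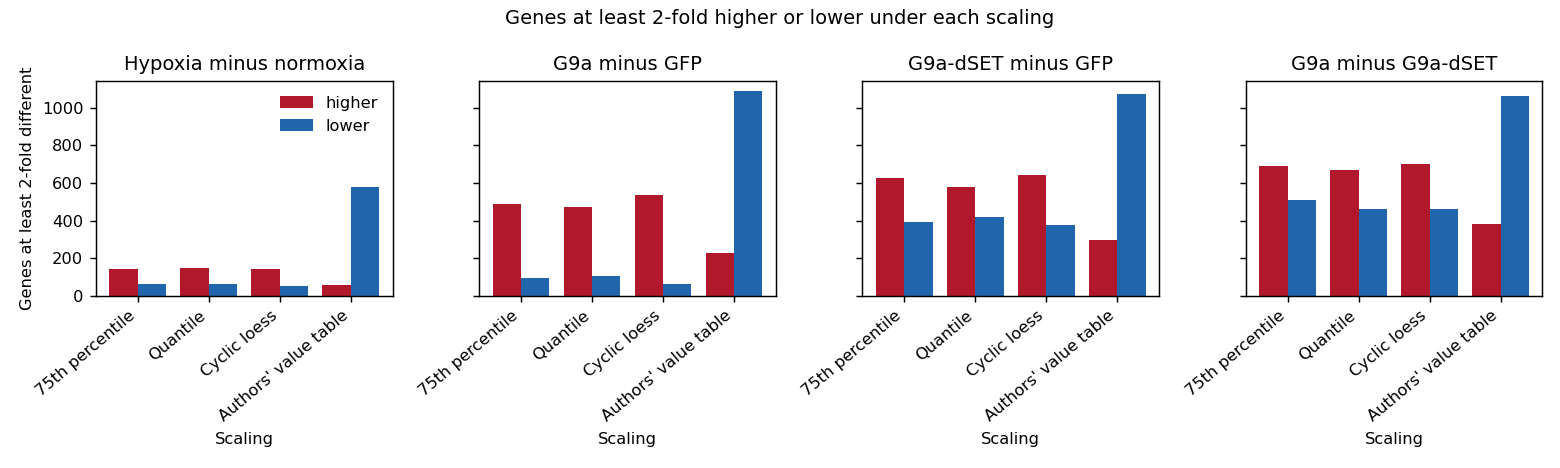
Number of genes at least 2-fold higher (red) or lower (blue) on the vertical axis under 4 scalings on the horizontal axis, in the 4 comparisons. In hypoxia 144 genes were higher and 60 lower after scaling to the 75th percentile, and 55 were higher and 579 lower in the authors' value table.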

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

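All tests in this part were chosen after the patterns they weigh were seen, including those that use cyclic loess, which had been planned as a setting; only the values of the detection floor test and the SLC39A10 test had not been seen when these tests were written. With 1 array per group, each difference between groups given here was not tested.

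The list of immediate early genes was singled out because its median against GFP was positive with G9a and negative with G9a-dSET; the median of G9a against G9a-dSET was 0.53. Cancer-testis and germline genes were singled out for the same difference between groups, with a median of 0.17 for G9a against G9a-dSET over partly other genes. With normexp the G9a-dSET medians of these lists were 0.03 and 0.04, so the opposite signs were not kept. That setting adds the same offset to arrays of unlike brightness, and whether the offset turned the signs was not tested. Probes without a gene name, which no comparison of the report uses, were at least 2-fold different in 104 cases in hypoxia, 392 with G9a, 590 with G9a-dSET and 563 between G9a and G9a-dSET.

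In the authors' value table, genes lower than in normoxia far outnumbered genes higher than in normoxia. The divisor of each array lay within 0.493% of the median signal of the probes above background, and with 1 common floor the normoxia array's share of such probes exceeded the mean of the others by 0.0576 percentage points instead of 6.80 with each array's own floor. The excess of lower genes is therefore consistent with a divisor that depends on how many dim probes each array counts. The divisors moved the comparisons with normoxia by -0.50 in hypoxia, -0.50 with G9a and -0.29 with G9a-dSET. A fall of RNA per cell shared by all expressed genes would be divided out with each array's own number. The excess is therefore no measure of such a fall. Whether RNA per cell fell stays open, because 0 spike-in probes were above background on all 4 arrays.

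The median of the stress response list was higher than with GFP on both construct arrays, though members differed between them: HSPA5 stood at -0.71 with G9a and 0.76 with G9a-dSET, and DDIT3 at 1.88 and -0.53. An intensity-dependent difference between arrays does not account for this, since the smaller of the list medians was 0.49 after cyclic loess. Low values of these genes on the shared normoxia array do not account for the G9a array, whose median was 0.36 with the hypoxia array as reference (random lists -0.14 to 0.21), but could account for the G9a-dSET array, at 0.14 (random lists -0.11 to 0.39). This test was first run on the smaller value alone and was divided by array after both were seen, and hypoxia itself had 8 of 21 of these genes at least 1.5-fold higher, which lowers both values. Slide and scan day cannot be told apart from the constructs, because 0 construct arrays lay on the slide of the GFP arrays, and an effect of the constructs stays open as untested.

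Metallothioneins were lower on the G9a-dSET array, and so were the zinc exporters SLC30A1 and SLC30A2, which are in no fixed list and were picked for the size of their difference (-3.03 each), so that they decide nothing about sequence shared between metallothionein paralogs. An intensity-dependent difference does not account for the metallothionein list, whose median was -1.88 after cyclic loess. For the 7 of 9 compared metallothioneins that were at least 1.5-fold lower, shared sequence cannot be told apart from separate differences, because no probe sequence was in the files. Less zinc in the cells of that array is a hypothesis that could account for the pattern: SLC39A10, a zinc importer known to be induced by low zinc, was higher there than on every other array, by 0.99 at least. This 1 gene decides little. The limit of the test was 1.5-fold, and 2012 of 14613 genes were that much higher there than with GFP. SLC39A10 also stood at -3.53 on the G9a array against -2.75 on the normoxia array. Metallothioneins with G9a had a median of -0.15, inside the range of random lists (-0.24 to 0.27). Whether the construct or the culture of the G9a-dSET array lies behind the pattern was not tested.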

How the results depend on the processing

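Chosen after the data were seen were normexp, the common detection floor and the 75th percentile over probes above background on all arrays; the other settings were planned. No paired analysis was possible because each group has 1 array. Quantile normalization, cyclic loess, the mean over a gene's probes, the common floor and the 75th percentile over probes above background on all arrays kept all 11 counts within 1.5 times and all 4 EHMT2 values within their error. Counts are given below in the order hypoxia lower and higher, G9a lower and higher, G9a-dSET lower and higher, G9a against G9a-dSET lower and higher, then genes lower in both hypoxia and G9a, those of them not shared with G9a-dSET, and genes higher in both, leaving out counts that stayed within 1.5 times. With normexp they were 18 and 47, 22 and 203, 128 and 1216, 191 (higher), then 1 lower in both and 5 higher in both; EHMT2 stood at 3.28 for G9a against GFP and 3.28 for G9a against G9a-dSET. With normexp the sign turned for CRABP2 (0.0833), CD3E (0.36) and LIF (0.50) in G9a-dSET against GFP. It also turned for CDKN1A (-0.27) in G9a against G9a-dSET. These comparisons all hold the G9a-dSET array, the dimmest, and normexp adds the same offset of 50 on every array. Whether this offset turned the signs was not tested. With no filter on dim probes the counts were 423 and 580, 678 and 2416, 1279 and 1125, 1040 and 1458, then 148, 19 and 250, since probes near background then count. With detection required on both arrays, 293 genes were higher with G9a and 0 were lower in both, since fewer genes were compared. With the authors' value table the counts were 579 and 55, 1089 and 227, 1077 and 297, 1065 and 381, then 105, 37 and 3, and EHMT2 stood at 0.0027 in hypoxia, 3.14 with G9a, -0.34 with G9a-dSET and 3.48 for G9a against G9a-dSET, since each array is then divided by another number. At a limit of 1.5-fold the counts were 398 and 353, 777 and 1281, 1599 and 2012, 1972 and 1931, then 57, 21 and 83; at 3-fold they were 7 and 46, 8 and 201, 60 and 148, 71 and 190, then 1 lower in both and 2 higher in both. Over all settings, 1042 list medians stayed within their spread and 262 moved, and 1658 values of named genes stayed, 391 moved and 4 turned. On the raw spot median minus the local background, the median SD of repeated spots rose on every array, most on the G9a-dSET array, from 0.07 to 0.22. The planned normexp on the spot mean was not run because the files hold no spot mean, scaling to spike-ins was not run because they lay near background, and slide as a block was not run because no group has a replicate. Signal over background limits the dim genes: 40.7% of probes on the hypoxia array and 40.9% on the G9a array were not well above background.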

Other observations

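This part reports values with no test. With G9a, HIF targets in glycolysis and glucose uptake had a median of 0.17 (random lists -0.16 to 0.14), with 3 of 22 at least 1.5-fold higher and 0 lower. Other HIF targets had a median of 0.10 with G9a, inside the range of random lists, while single members were higher there, such as ANGPTL4 (0.99), BHLHE40 (0.93) and VEGFA (0.81); the collagen-modifying enzyme PLOD2 stood at -0.75. HIF3A, a member of the HIF family, stood at 2.72 with G9a. The list of HIF pathway regulators that holds it had a median of -0.07 (random lists -0.25 to 0.28). Of its 11 genes, 9 were less than 1.5-fold different. Neuronal markers had medians of 0.45 with G9a (random lists -0.28 to 0.28) and 0.53 with G9a-dSET (random lists -0.31 to 0.45), with CHGA at 0.62 and 0.66 and SYP at 0.68 and 0.86. Mitosis genes in hypoxia had a median of 0.10 (random lists -0.09 to 0.05), with 0 of 34 at least 1.5-fold higher or lower.

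Among genes well above background on only 1 array of a pair, PABPN1L was at least 45.9-fold and PKD1L3 at least 33.2-fold higher with G9a than with GFP, NWD1 was at least 13.1-fold higher in hypoxia, and the transcription factor SOX11 was at least 9.82-fold higher with G9a-dSET. At least 2-fold lower with both constructs were 30 genes (2.55 expected from independent lists), and at least 2-fold higher with both were 89 (10.5 expected); these comparisons share the normoxia array. Among the 12727 genes well above background on all arrays, 19 were lower and 67 higher with both constructs, against 0 and 0 in unchanged arrays simulated with either noise, and the covariance was 0.0633 against 0.00431 with repeated-spot noise and 0.0235 with the spread between hypoxia and normoxia, which holds the differences of hypoxia itself. The correlation of 0.299 lay below the simulated 0.376 and 0.500. The SD of the differences was 0.43 with G9a and 0.53 with G9a-dSET, against 0.30 in hypoxia, whose spread set the wider noise. These SDs hold any effects of construct and slide. Both noise levels were thus narrower than the spread of these arrays, and the simulated counts of 0 are no level of no change for them. Differences between slides and outlying values of single genes on the shared array were not simulated and are not excluded.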
